A study of Campeiostachys nutans with 6 samples.

How the data were processed

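RNA from leaves of Campeiostachys nutans, a perennial grass of the wheat tribe, was measured in 6 libraries, 3 of control seedlings and 3 of seedlings kept with 200 mM salt for 5 days, all 28 days old and wild type per the labels. Groups follow the sample titles and the treatment tags. The age tag of the salt samples describes them as kept without salt, which conflicts with both, and it was not used. The labels do not say whether the libraries of a group came from separate plants, pots or trays, so p-values measure the spread between these samples, which may be technical.

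Per the labels' protocols, total RNA was extracted with Trizol and sequenced for a de novo transcriptome on an Illumina NovaSeq instrument. The gene identifiers in the deposited table have the form that the Trinity assembler gives. The read trimming, the quantifier, the assembly version and the differential test are not given in the sources used here. Per the file headers, the authors' table gives for each of 85297 assembled genes an estimated count and a TPM value per library, mean TPM per group, a log2 fold change, a p-value and its FDR, a significance call, the length in bases, and best-hit descriptions, orthologous groups, KEGG, GO and Pfam terms. The estimated counts were deposited without normalization and not all of them are whole numbers. They were rounded before any count test. The TPM columns, as deposited by the authors, sum to between 988629 and 992961 per library. No genome was used here, so no coordinates are given. An assembly can split a locus into several genes and can merge or divide the copies of a polyploid genome, so values of near-identical family members are uncertain and members of a list are not independent.

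Library totals were 18.1, 19.2 and 15.04 M (mega) estimated counts in control libraries 1, 2 and 3, and 14.99, 15.5 and 16.003 M in salt libraries 1, 2 and 3. The intervals and floors given for low counts use a confidence level of 95% and a floor of 3 counts over a group, and cover counting error only. Every value column of the table was matched to a sample or to the authors' own comparison.

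Genes were filtered with filterByExpr, which left 42879 genes holding 98.5% of the counts, scaled with TMM, and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), two-sided, with treatment as the only term and Benjamini-Hochberg adjustment, at an adjusted p threshold of 0.05. The common dispersion was 0.314. The SE given with a log2 fold change is its absolute value over the square root of the quasi-likelihood F. It is approximate, above all for genes with few counts in a group. Gene lists were tested with camera in limma 3.58.1 with an inter-gene correlation of 0.01, and adjusted over 36 lists. A gene joined a list where its description matched the list's pattern. For each list the members were also adjusted over the list alone. Camera was run again with an estimated correlation, and fry was run on the same lists. Fry's p tests whether a list moves on balance in one direction and does not compare it with other genes. Enrichment of GO and KEGG terms used the one-sided hypergeometric form of Fisher's exact test over terms with at least 10 tested genes, higher and lower genes apart.

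The lists, the tests, the leave-one-out fits and the rule for naming genes were fixed before the data were examined. The rule names the best expressed homolog of each protein in the study's title and of the SOS pathway, the best expressed member and the called member with the largest fold of each list, the 10 called genes with the largest fold in each direction among those with a mean of at least 5 CPM, groups that do not overlap and an informative description, 1 gene per description, and the best expressed gene of each group. Because edgeR's quasi-likelihood test called 0 genes over all tested genes, the parts of the rule that need calls name none. In their place, chosen after seeing the data, stand members that passed when adjusted over the list alone, and genes with an unadjusted quasi-likelihood p under 0.05 and a DESeq2 adjusted p under 0.05. A CIPK4 homolog was not analysed here, since no description matched it.

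Alternatives fixed in advance were DESeq2 1.42.0, no filter, a filter of at least 30 counts in 3 libraries, prior counts of 0.1 and 5, a replicate block, limma-voom, each library left out in turn, a fold threshold of 1 on the log2 scale, counts summed by best hit, and fry, an estimated correlation and members of 1 list only for the lists. Alternatives added after seeing the data were edgeR's likelihood-ratio test, limma-voom with quality weights, fits without genes of animal, fungal, bacterial or viral best hit, fits of genes with a grass best hit only, library totals or upper-quartile scaling alone, camera on log2 CPM, enrichment on DESeq2 calls, and fits of 2 control libraries against salt libraries 1 and 3, or of the 3 control libraries against salt library 1 or 3 alone, used to place salt library 2 beside a library held out of the choice of genes. List medians against 2 control libraries, and shares of the change over all tested members of the LEA and photosystem lists, were added for the same purpose. Shares of the change were taken on the linear scale. The origin of a gene was read from its best hits: a gene is called arthropod-like here where its Swiss-Prot hit is an arthropod protein and its Nr hit is not from a grass. Median log2 fold changes over all tested genes were -0.04 with TMM, -0.27 with library totals alone and -0.13 with upper-quartile scaling, so list medians under those scalings are read relative to these values.

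The tests were checked on simulated counts drawn for the 42879 tested genes from their control means, dispersions and the library sizes. For the gene tests, the moved genes were drawn from those above a floor of mean expression in control. The recovery therefore does not cover genes almost absent from control, such as the bHLH130 homolog and DHN2. Genes were drawn independently and no library was set apart as salt library 2 is, so recovery in the real data may differ. The quasi-likelihood test recovered 7% of 100 genes moved by 2 on the log2 scale and 66% of 100 genes moved by 4, with 4 false calls. DESeq2 recovered 43% and 87%, with 89 false calls. The list test recovered the moved list and called 0 of 35 lists that were not moved, but the genes were simulated independently, so this gives no false-call rate for correlated genes. Other splits of the 6 libraries into 3 and 3 gave 4 to 20 lists past the threshold. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for summaries.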

Results

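Leaf transcriptomes of Campeiostachys nutans, a perennial forage grass related to wheat and barley, were compared between seedlings given 200 mM salt for 5 days and control seedlings, with 3 libraries per group. The seedlings were 28 days old. The table holds 85297 assembled genes, with 18.1, 19.2 and 15.04 M estimated counts (M, mega) in control libraries 1, 2 and 3 and 14.99, 15.5 and 16.003 M in salt libraries 1, 2 and 3. The title of the study names a bHLH130 transcription factor, the calcium sensor CBL10 and the kinase CIPK4 in the SOS pathway of sodium export, and the comparison of salt with control leaves addresses how these and other genes respond to salt.

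In salt-treated leaves, genes for LEA proteins and dehydrins, which protect cells during water loss, were higher as a group, together with genes of abscisic acid synthesis and signalling, and genes of the photosystems and the Calvin cycle were lower. Among 62 tested LEA and dehydrin genes, the median log2 fold change was 3.44. Among 113 photosystem and antenna genes it was -1.58. These list calls rest on camera with a preset correlation of 0.01. With an estimated correlation the adjusted p was 0.367 for the LEA, photosystem and Calvin cycle lists and 0.424 for both ABA lists, and 0 lists passed with fry. These are results for groups of genes: edgeR's quasi-likelihood test called 0 of 42879 genes after adjustment over all tested genes (8375 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.104). DESeq2, run on the counts without that filter, called 5005 of 56656 genes, so the 2 results differ in their genes as well as in the test. Salt library 2 lay between the control libraries and the other salt libraries on the first principal component, and outside both groups on the second, at -135 against -73.2 to 147. Without it the quasi-likelihood test called 6458 of 47807 tested genes, 4603 higher and 1855 lower in salt. Leaving out the salt library nearest to the controls lowers the p of genes that follow this pattern. Values without it are therefore not independent support.

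**Figure D1:**
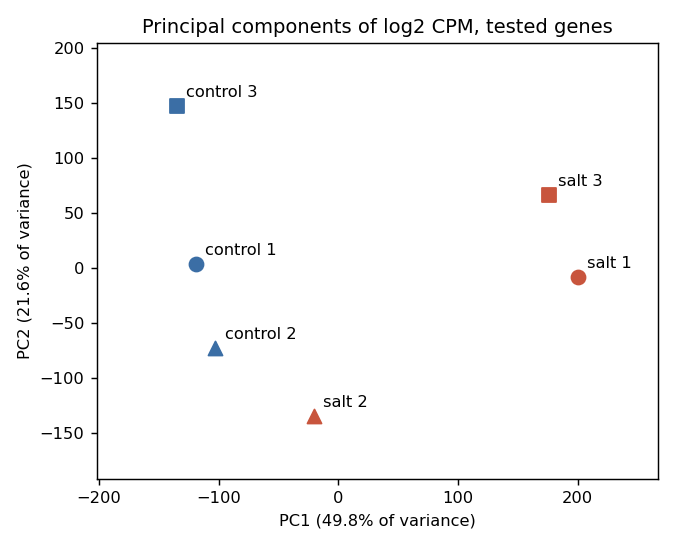
First and second principal component of log2 CPM over the 42879 tested genes, 1 point per library, in blue for control and red for salt. On the first component, with 49.8% of the variance, the control libraries sit between -134 and -103, salt library 2 at -20.4, and the other salt libraries at 176 and 201. On the second, with 21.6%, salt library 2 sits lowest, at -135.

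The single tested gene described as bHLH130 (TRINITY_DN37187_c0_g1, 440 bases assembled) was at 0.267 ± 0.287 TPM in control and 73.2 ± 55.0 TPM in salt leaves (SD, n = 3 each). Its log2 fold change was 9.005, with an approximate standard error (SE) of 1.30. The control libraries held 8, 2 and 0 counts of it, so the size of the fold is uncertain. Its adjusted p was 0.104 over all genes and 0.0153 adjusted over the list of bHLH factors alone, and over all genes 0.00353 without salt library 2 and 4.51e-14 with DESeq2. The salt libraries stood at 81.3, 14.5 and 123.7 TPM. The single tested gene described as CBL10 (TRINITY_DN47695_c0_g1) was at 0.660 ± 0.159 TPM in control and 3.57 ± 2.44 TPM in salt (SD, n = 3), with 5.6, 0.9 and 4.2 TPM in the salt libraries. Its log2 fold change of 2.66 (SE 0.75) did not pass quasi-likelihood adjustment over all genes (adjusted p = 0.139) or over the list of CBL sensors alone (adjusted p = 0.0881). Over all genes it passed without salt library 2 (adjusted p = 0.00791) and with DESeq2 (adjusted p = 0.00815). For both title genes salt library 2 was the salt library nearest to control, so its removal favours a lower p. The authors' deposited table calls both genes significant.

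Like every tested gene, the remaining SOS components did not pass the quasi-likelihood test with all libraries after adjustment over all genes. SOS1, the plasma membrane sodium exchanger, had 11 tested assembled genes, of which 0 were called by edgeR or DESeq2, and log2 fold changes from -1.33 to 0.64. Its best expressed gene was at 11.7 ± 2.16 TPM in control and 14.0 ± 3.24 TPM in salt (SD, n = 3). CIPK24, the SOS2 kinase, was at 6.20 ± 0.958 and 5.73 ± 0.612 TPM. CBL4, the SOS3 sensor, was at 9.16 ± 1.76 and 5.72 ± 0.566 TPM in its better expressed copy, with a log2 fold change of -0.51, and the other copy had one of 1.58. Neither copy was called by edgeR or DESeq2. As lists, the 10 CBL sensors (camera adjusted p = 0.975), the 57 CIPK kinases (adjusted p = 0.104) and 22 sodium and proton exchangers (adjusted p = 0.893) were not past the threshold. The best expressed exchanger, the vacuolar NHX2, was at 21.4 ± 6.22 TPM in control and at 105.5, 15.5 and 72.5 TPM in the salt libraries, with a log2 fold change of 1.84 (SE 0.68, adjusted p = 0.211). Its adjusted p was 0.00768 without salt library 2 and 0.0731 with DESeq2, and the authors' deposited table calls it significant. The CIPK list passed upward with quality weights (adjusted p = 0.0141). Its best expressed member, CIPK9, went from 67.8 ± 16.3 to 146 ± 48.4 TPM (SD, n = 3), with a log2 fold change of 1.35 (SE 0.41, adjusted p = 0.153). The adjusted p of CIPK9 was 0.0186 without salt library 2 and 0.0302 with DESeq2, and the authors' deposited table does not call it. Adjusted over the list alone, 0 CIPK members passed, against 14 without salt library 2 and 0 without each other library. DESeq2 called 4 higher and 0 lower.

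**Figure D2:**
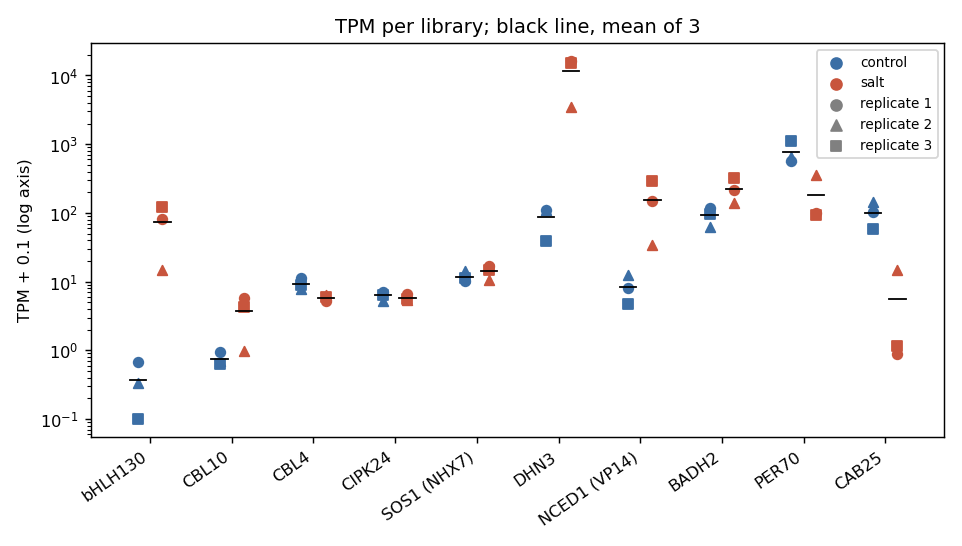
TPM plus 0.1 on a log axis for title genes and representative members of the gene lists, 1 point per library (blue control, red salt; circle, triangle and square for replicates 1, 2 and 3) with the group mean as a black line. The bHLH130 homolog reaches 14.5 TPM in salt library 2 and 123.7 TPM in salt library 3, against at most 0.57 TPM in control.

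LEA proteins and dehydrins showed the clearest rise. Of the 62 tested members, 40 rose and 2 fell when adjusted over the list alone, and 20 did not pass. DHN3, a dehydrin and the best expressed member, rose from 86.6 ± 41.6 TPM to 16098, 3493 and 14971 TPM in the salt libraries, a log2 fold change of 6.88 (SE 1.02, adjusted over the list alone p of 0.00258). The pooled counts of the dehydrin DHN2, with 1 count in control, gave a ratio of salt to control of 9276 with a 95% counting interval of 1664 to 3.66e+05. The camera test of the list gave an adjusted p = 1.03e-26, and an adjusted p = 0.367 with an estimated correlation. Relative to the control mean, the median member stood 4.08, 1.82 and 4.05 higher on the log2 scale in salt libraries 1, 2 and 3.

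Genes of abscisic acid, the hormone of water deficit, were also higher. In ABA signalling, 23 of 52 members rose and 1 fell when adjusted over the list alone, and 28 did not pass. A protein phosphatase 2C of the clade that restrains ABA signalling, the best expressed member, went from 30.4 ± 13.1 to 329 ± 239 TPM (SD, n = 3), with a log2 fold change of 3.64. In ABA synthesis and turnover, 8 of 24 members rose and 1 fell, and 15 did not pass. The 9-cis-epoxycarotenoid dioxygenase VP14, which catalyses the committed step of ABA synthesis, rose with a log2 fold change of 4.53 (SE 0.94), and the ABA 8'-hydroxylase CYP707A7, which breaks ABA down, rose with 4.53 (SE 1.18). Camera gave an adjusted p = 1.05e-09 for signalling and 3.32e-05 for synthesis, and an adjusted p = 0.424 for both with an estimated correlation. Leaving out control library 1 left 0 passing members in both lists, and leaving out salt library 2 gave 40 and 15. For synthesis, 5 passed without control library 2 and 0 without control library 3.

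Proline and glycine betaine are compatible solutes. Of 27 genes of their metabolism, 10 rose and 2 fell when adjusted over the list alone, and 15 did not pass (camera adjusted p = 0.000112, and adjusted p = 0.367 with an estimated correlation). The betaine aldehyde dehydrogenase BADH2 rose from 92.0 ± 27.5 to 226 ± 93.1 TPM (SD, n = 3), with 137.9 TPM in salt library 2. Without control library 2, 7 members passed. The list of sugar osmolytes and fructans did not pass (adjusted p = 0.0537), but it passed upward without salt library 2 (adjusted p = 0.0125) or control library 1 (0.0129), with the stricter filter (0.00485), limma-voom (0.0298), quality weights (0.00814) and camera on log2 CPM (0.0301). It also passed without genes of animal, fungal, bacterial or viral best hit (adjusted p = 0.0320) and with grass-hit genes only (0.0394, and 0.0151 without salt library 2).

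Photosystem and antenna proteins made up the clearest fall. Of 113 tested members, 78 fell and 7 rose when adjusted over the list alone, and 28 did not pass. The best expressed chlorophyll a-b binding protein went from 5263 ± 792 to 1208 ± 811 TPM (SD, n = 3), a log2 fold change of -2.07 (SE 0.57). CAB25 went from 101 ± 42.2 to 5.56 ± 8.02 TPM. Camera gave an adjusted p = 2.29e-29, and an adjusted p = 0.367 with an estimated correlation. In salt libraries 1, 2 and 3 the median member differed from the control mean by -2.01, -1.18 and -1.56 on the log2 scale. The count of passing members was 36 without control library 2 and 56 without salt library 1.

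Other plastid lists were lower too. Of 48 Calvin cycle genes, 16 fell and 2 rose when adjusted over the list alone (camera adjusted p = 2.89e-08, and adjusted p = 0.367 with an estimated correlation). The small subunit of Rubisco, the best expressed gene of the control leaves, was at 28640 ± 5727 TPM in control and at 2685, 9566 and 4664 TPM in the salt libraries. Of 102 plastid ribosomal protein genes, 29 fell and 3 rose (adjusted p = 5.33e-06, and adjusted p = 0.507 with an estimated correlation). Of 49 chlorophyll synthesis genes, 1 fell (adjusted p = 0.000123, and adjusted p = 0.424 with an estimated correlation). Leaving out control library 2 or salt library 1 gave 11 passing Calvin cycle genes. For plastid ribosomal proteins, 0 passed without control library 1, control library 2, salt library 1 or salt library 3, and for chlorophyll synthesis 5 passed without salt library 2 and 0 without any other library.

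Several families of transcription factors were higher as lists. Of 87 WRKY genes, 24 rose and 1 fell when adjusted over the list alone (camera adjusted p = 5.07e-09, and adjusted p = 0.424 with an estimated correlation). WRKY76 went from 2.16 ± 1.18 to 77.3 ± 61.5 TPM (SD, n = 3). Of 187 genes of ethylene synthesis and ERF factors, 33 rose and 5 fell (adjusted p = 9.69e-07, and adjusted p = 0.445 with an estimated correlation), among them DREB1C, of a family known from cold and drought responses, with a log2 fold change of 6.04 (SE 1.19). Of 89 NAC genes, 21 rose and 3 fell (adjusted p = 0.000112, and adjusted p = 0.622 with an estimated correlation). These counts rested on the libraries used. Without salt library 2 they were 38, 96 and 39. Without control libraries 1, 2 or 3 or salt libraries 1 or 3, they were 11, 12, 12, 11 and 15 for WRKY, 0 in each case for ERF, and 0, 1, 0, 0 and 0 for NAC. The bHLH list was not past the threshold (adjusted p = 0.238), with 4 members higher and 2 lower when adjusted over the list alone, and neither were MYB factors (adjusted p = 0.653). In the bHLH list, 32 members passed without salt library 2, 20 higher and 12 lower, and 0, 5, 3, 1 and 1 without control libraries 1, 2 or 3 or salt libraries 1 or 3. Without control library 2 the bHLH list passed upward (adjusted p = 0.0166).

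**Figure D3:**
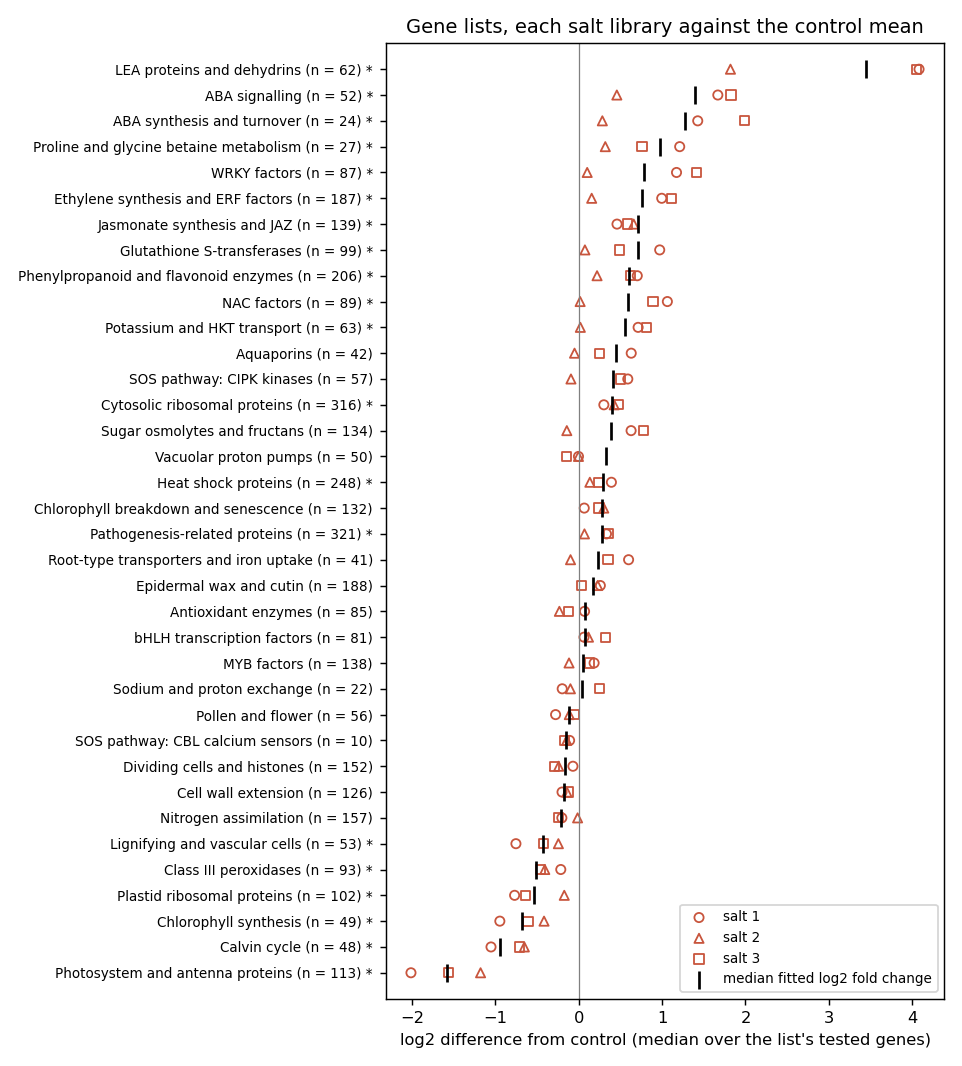
Median log2 difference from the control mean over the tested members of each gene list, for each salt library (circle, triangle and square for salt libraries 1, 2 and 3), with the median fitted log2 fold change as a black bar. An asterisk marks the 20 of 36 lists with a camera adjusted p under 0.05. For LEA proteins and dehydrins salt library 2 sits at 1.82 against 4.08 and 4.05, and for photosystem proteins at -1.18 against -2.01 and -1.56.

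For other lists past the camera threshold, few members passed on their own. Phenylpropanoid enzymes (2 of 206 members higher, adjusted p = 0.000123, and adjusted p = 0.424 with an estimated correlation), glutathione S-transferases (4 of 99, adjusted p = 0.000259, and adjusted p = 0.424) and jasmonate genes (0 of 139, adjusted p = 0.000266, and adjusted p = 0.367) were higher. Potassium and HKT transporters (0 of 63, adjusted p = 0.0147, and adjusted p = 0.424), heat shock proteins (1 of 248, adjusted p = 0.0172, and adjusted p = 0.367) and pathogenesis-related proteins (5 of 321 higher and 2 lower, adjusted p = 0.0281, and adjusted p = 0.424) followed. Class III peroxidases were lower (4 of 93 lower and 1 higher, adjusted p = 0.00574, and adjusted p = 0.510), the second value in each case being that with an estimated correlation. Without salt library 2 the counts of passing members were 45, 39, 36, 19, 22, 78 and 34 in this order, and without control library 1, 2 or 3 or salt library 1 or 3 they lay between 0 and 4. Without salt library 2 the camera call was lost for heat shock proteins (adjusted p = 0.143) and pathogenesis-related proteins (adjusted p = 0.0982). The camera call was also lost for heat shock proteins without control library 1 (adjusted p = 0.113), for peroxidases without control library 2 (adjusted p = 0.139), and for pathogenesis-related proteins without control library 2, control library 3 or salt library 3 (adjusted p = 0.188, 0.167 and 0.0655). With grass-hit genes only it was lost for heat shock proteins (adjusted p = 0.0859), with quality weights for peroxidases (adjusted p = 0.104) and pathogenesis-related proteins (adjusted p = 0.0541), and without a filter for the latter (adjusted p = 0.0747).

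Cytosolic ribosomal protein genes were higher as a list (316 members, adjusted p = 3.79e-07, and adjusted p = 0.424 with an estimated correlation), with 0 members passing when adjusted over the list alone. This count was 36 without control library 1, 12 without salt library 2 and 28 without salt library 3. The list mixes genes of different origin by best hit. Its 204 members with a grass hit had a median log2 fold change of 0.17, while 42 members with fungal hits had a median of 4.02 and 32 with arthropod hits a median of 1.52. The camera adjusted p was 0.157 with grass-hit genes only and 0.0861 without genes of animal, fungal, bacterial or viral best hit.

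Among the lists for other cell types, lignifying and vascular cells were lower (53 members, adjusted p = 0.0189, and adjusted p = 0.622 with an estimated correlation), with 0 members passing. Without control library 1 or 2 the call was lost (adjusted p = 0.143 and 0.224). It was also lost with members of 1 list only (adjusted p = 0.127), the stricter filter (0.134), limma-voom (0.0997), quality weights (0.104) and camera on log2 CPM (0.0585). The count of passing members was 8 without control library 3 and 1 without salt library 2. Epidermal wax and cutin (adjusted p = 0.145), dividing cells and histones (adjusted p = 0.186), root-type transporters (adjusted p = 0.313) and pollen and flower (adjusted p = 0.313) did not pass, nor did aquaporins (adjusted p = 0.156), senescence (adjusted p = 0.313), cell wall extension (adjusted p = 0.507), nitrogen assimilation (adjusted p = 0.507), antioxidant enzymes (adjusted p = 0.629) or vacuolar proton pumps (adjusted p = 0.856). Cell wall extension passed downward without control library 3 (adjusted p = 0.00210), and aquaporins upward with quality weights (adjusted p = 0.0442). Median, mean and test differed in sign for antioxidant enzymes, sodium and proton exchange, CBL sensors and nitrogen assimilation.

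Genes with arthropod best hits took 0.451%, 0.707% and 0.113% of the counts in control libraries 1, 2 and 3 and 0.605%, 2.19% and 0.272% in salt libraries 1, 2 and 3, which is 0.424 ± 0.298% against 1.02 ± 1.03% (SD, n = 3, exact permutation p = 0.5, with 0.1 the smallest that 3 against 3 allows, two-sided). A set of 26 genes for muscle proteins without a grass hit, such as myosin heavy chain, troponin T and tropomyosin, not all of them with arthropod best hits, took 0.265% in salt library 2 and at most 0.0580% elsewhere. Genes with best hits in other animals took 1.63% in salt library 2 and at most 0.585% elsewhere. Grass-hit genes took 85.3% there and at least 89.2% elsewhere, and genes without a hit 8.51% there and at most 7.57% elsewhere. Genes with fungal hits took 0.340 ± 0.0243% in control and 0.453 ± 0.0230% in salt (SD, n = 3, exact permutation p = 0.1, the smallest possible). In salt library 2 the LEA and photosystem lists also moved least, as given above by their medians, while the median of the jasmonate list was highest there (0.66 against 0.46 and 0.59 in salt libraries 1 and 3).

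**Figure D4:**
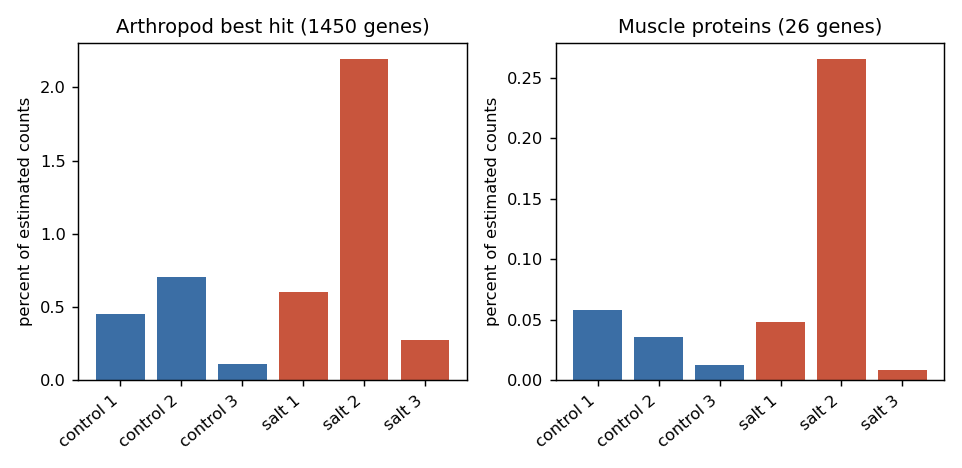
Percent of estimated counts per library in genes with arthropod best hits (left, 1450 genes) and in genes for muscle proteins without a grass hit (right, 26 genes), blue for control and red for salt. Salt library 2 holds 2.19% and 0.265%, above each of the other libraries.

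The largest changes by name, chosen by DESeq2 and by the unadjusted quasi-likelihood test because the latter made no calls, included the bHLH130 homolog, DHN2, a group 3 LEA protein, the peroxiredoxin PER1 and the plastid protease FTSH6 among the 10 higher genes, and the germin-like GER5, CAB13, CAB25 and PRX112, a peroxidase, among the 10 lower genes. PER1 went from 0.123 ± 0.116 to 75.3 ± 54.4 TPM and FTSH6 from 0.070 ± 0.026 to 23.1 ± 23.4 TPM. GER5 went from 133 ± 140 to 1.48 ± 2.28 TPM (SD, n = 3 each), and its control libraries spanned 285.4 to 11.3 TPM. Across all tested genes, 4391 had every salt library above every control library and 6352 had every salt library below, together 25.1% of genes where chance gives 10% on average. Genes of a library vary together, so a single split can lie far from that average. Other splits gave 436 to 5832 genes at an unadjusted quasi-likelihood p under 0.05, where 2144 are expected by chance. By that p in the real split, more genes were higher (4726) than lower (3649), the reverse of the balance above.

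The authors' deposited table calls 4042 genes significant, 3138 higher and 904 lower in salt. The quasi-likelihood test shared 0 of these calls after adjustment, since it made none. Of the 3229 deposited calls that it tested, 3229 had the same sign and 3217 an unadjusted p under 0.05. DESeq2 called 92.5% of the deposited calls with the same sign. The deposited calls come from the same libraries, so these overlaps are not independent support. With 0 calls, no functional term was enriched in the quasi-likelihood result. Among DESeq2 calls, 134 terms passed a Fisher's exact test, led by chloroplast thylakoid membrane among lower genes (104 of 325 tested genes, 13.5-fold) and response to water deprivation among higher genes (73 of 285, 3.90-fold). Of the 20 lists past the camera threshold, 0 passed with an estimated correlation, and fry's lowest adjusted p was 0.0623.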

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

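The count of 0 called genes with edgeR's quasi-likelihood test (8375 at an unadjusted p under 0.05) held with no filter, a stricter filter, other prior counts, summed best hits, limma-voom, other scalings and fits of plant-like genes only, and leaving out 1 library gave 0 to 6458 calls (0 to 4603 higher, 0 to 1855 lower), the highest without salt library 2 and 0 without each other library. DESeq2, run without the filter, called 5005 of 56656 genes (3939 higher, 1066 lower). Added after seeing the data, over 42879 genes, edgeR's likelihood-ratio test called 3512 (2539 and 973) and limma-voom with quality weights 8394 (4907 and 3487). The latter gave salt library 2 a weight of 0.225. The share of deposited calls shared was 92.5% with DESeq2, 72.7% with the likelihood-ratio test, 69.1% with quality weights, and 0 to 81.4% when 1 library was left out. Enriched terms numbered 134 among DESeq2 calls, 133 with a fold threshold, 87 with 1 gene per best hit, and 145 without salt library 2.

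Lists past the threshold numbered 18 to 20 under the alternatives, except 0 with an estimated correlation and 0 with fry. With a replicate block the test called 0 genes and 20 lists. Pairing by number was not used in the main fit, since the labels do not say that the numbers mark a shared pot, tray or day. Same-numbered libraries deviated with correlations of -0.09, 0.07 and 0.29, and other pairs with -0.20 to 0.15. Deviations within a group of 3 depend on each other, so these values do not decide on pairing. The ribosomal list turned lower, with an adjusted p of 0.911, on grass-hit genes without salt library 2. Named genes that changed sign all had small fold changes: CIPK24 (-0.15 with library totals), CBL2 (-0.20 to 0.11 leaving out 1 library, 0.14 with quality weights), LOX2.1 (-0.63 to 0.15), TIP4-1 (-0.43 to 0.21, 0.19 with quality weights), a Bowman-Birk inhibitor (-0.29 to 1.03, -0.0751 with library totals) and an asparagine synthetase (-0.0401 to 0.32, -0.0647 with library totals). For differences between tools, and for the changes of sign, the cause was not tested. Whole-read recovery was not run, since counts are given. Simulated counts gave the quasi-likelihood test 7% recovery of changes of 2 on the log2 scale. A gene that did not pass is therefore not shown to be unchanged. The simulation drew genes independently and moved 100 genes by each size, with no library set apart like salt library 2. Its recovery and false-call counts may therefore differ from those in the real libraries. In the same simulation DESeq2 made 89 false calls, more than its threshold allows, so a gene or term that rests on DESeq2 alone is uncertain.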

Other observations

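The tests of explanations in this part, the split counts included, were written down after the values they concern had been seen. Further members of the gene lists are given here with their values. The senescence-specific protease SAG39 went from 123 ± 19.0 TPM in control to 626.5, 1935.4 and 663.0 TPM in the salt libraries (log2 fold change 3.27, SE 0.53, adjusted over the list alone p of 0.0486), and was highest in salt library 2. In its list, 30 members passed without salt library 2 and 0 without each of the other libraries. The aquaporin PIP1-3 went from 28.8 ± 7.91 to 133 ± 58.4 TPM, and the cinnamyl alcohol dehydrogenase CAD5 from 34.8 ± 3.79 to 125 ± 17.1 TPM (SD, n = 3). A thaumatin-like protein went from 6.93 ± 2.31 to 258 ± 158 TPM.

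The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The quasi-likelihood test called 0 genes in all 10 splits. At an unadjusted p under 0.05 the real split gave 8375 genes and the highest other split 5832, so 1 split of 10 reached the real count. DESeq2 called 5005 genes in the real split and at most 1579 in another, again 1 of 10. For gene lists, the real split gave 20 past the camera threshold and another split, which groups salt library 2 with control libraries 1 and 2, also gave 20, so 2 of 10 reached it. The splits with the most genes at an unadjusted p under 0.05 after the real one, 5832, 5052 and 3589, are those that group salt library 2 with 2 control libraries.

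Salt library 2 lay between the control and the other salt libraries on the first principal component, but outside both groups on the second (-135). On the linear scale, its median share of the change was 0.0841 over 3613 higher and 0.592 over 1824 lower genes. These genes were called without salt library 2 and are among the 42879 tested genes. For the LEA list its log2 median was 1.82, against 4.08 and 4.05 in salt libraries 1 and 3. For the photosystem list it was -1.18, against -2.01 and -1.56, so the contrast between directions depends on the scale. With genes chosen without 1 control library, that library had median shares of -0.00279 to 0.0404 for higher and 0.205 to 0.319 for lower genes. In these fits salt library 2 had at least 0.0889 and 0.551. A control library under a salt label is argued against, since against 2 controls the LEA median minus the photosystem median was 2.87 to 3.45 in salt library 2 and -0.63 to 0.26 in a held-out control, a difference of at least 2.61 where the held-out controls spanned 0.89. RNA of other organisms as the whole explanation is argued against, since on grass-hit genes chosen with salt library 1 or 3 alone, salt library 2 showed at most 0.0851 of the change of the held-out salt library for higher genes and at most 0.630 for lower genes. RNA of control leaves mixed in as the whole explanation is argued against, since it needs 1 share for all genes, and over all tested members, whichever controls and salt libraries served as reference, the median share was 0.107 to 0.151 for the LEA list and 0.696 to 0.859 for the photosystem list, at least 0.545 apart. A weaker salt response of these plants may also give this pattern, and the labels give no dose or time that differs for this library.

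Genes with arthropod best hits took a larger share in some libraries, most in salt library 2. Arthropod RNA on the leaves may be the source, as a hypothesis, since genes for muscle proteins without a grass hit took 0.00861% to 0.265% of the counts. A set of 30 genes for cuticle and other arthropod proteins without a grass hit took 0.108% in salt library 2 and at most 0.0166% elsewhere. In salt library 2, 91.3% of 652 other arthropod-like genes were highest, against 7.06% of grass-hit genes, but this largely restates the larger share. For these 652 genes it cannot decide between arthropod RNA and conserved plant genes with an animal best hit. The ratio of muscle to other arthropod-like counts ranged from 0.0327 to 0.147 over the libraries, so 1 source in a fixed ratio is not enough. Whether salt-treated plants carried more is open (exact permutation p = 0.5, with 0.1 the smallest possible).

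Cytosolic ribosomal protein genes were higher in salt as a list with camera's preset correlation, and not past the threshold with an estimated one (adjusted p = 0.424). With grass-hit genes only the adjusted p was 0.157 and the median log2 fold change fell from 0.40 to 0.16, so ribosomal protein genes of animals or fungi in the list are a candidate explanation of the call. The list's median stood 0.443 above that of all tested genes with library totals alone, but scaling moves both alike, so this value decides nothing about scaling. All 42 members with fungal hits were higher at an unadjusted p under 0.05, against 16 higher and 9 lower among 204 with a grass hit. These 42 may follow a shared source in each library, so they are not independent results. They held 0.000273% to 0.00323% of the counts in control libraries and 0.00657% to 0.0352% in salt libraries. The filter could therefore keep members through the salt libraries alone, which favours a higher value in salt. The share of counts in genes with fungal hits was higher in each salt library than in each control library, with an exact permutation p = 0.1, the smallest possible, so this design cannot pass the threshold.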
